A study of Homo sapiens with 6 samples.

How the data were processed

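MicroRNA (miRNA) levels were measured by SYBR Green real-time PCR on ready-made miRCURY LNA panels (Exiqon) in 6 samples, per the labels: 3 of the human chondrosarcoma line JJ012 and 3 of the control chondrocyte line C28. Per the labels' protocols, 5000000 cells were seeded per dish and incubated for 24 h at 37 °C in 5% CO2, total RNA was extracted, and 20 ng of RNA per panel was polyadenylated and reverse transcribed. The labels' cell type entries name the JJ012 samples as chondrocytes and the C28 samples as chondrosarcoma, the opposite of the source names and cell line entries. Samples were grouped by their titles, which go with the cell line entries. Whether the triplicates were separate cultures is not given in the sources used here.

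The values analysed are signed fold changes from the authors' deposited table, 1 value for each of 325 miRNAs. Per the file headers, each is test over control by the 2^-ΔΔCt method, where Ct is the PCR cycle at which signal crosses a threshold. The labels' descriptions call the JJ012 samples test and the C28 samples control, so a positive value is read as higher in JJ012. The direction rests on the labels alone, which also call C28 a control. A lower level is written as minus the inverse ratio, since no deposited value lies between the positive and negative limits of an unchanged fold. The deposited table gives no error, p-value or number of wells for a miRNA. The reference behind ΔCt, the detection limit and the handling of undetected wells are not given in the sources used here. If 1 reference served every assay, it added the same constant to every log2 fold change, and the alternative zero points used here assume so. Amplification below doubling per cycle would make the folds overstate differences. The precision of each value is unknown.

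A second table held 6 columns of per-sample values whose names match no single sample's title, description or other label. Those columns were not used, since tying them to a cell line would have needed column order or the values themselves. When that table was opened to find its unit, it showed no reading for many miRNAs that have a fold change, and readings for others that have none. How those fold changes were obtained is not given in the sources used here, and the counts, extremes and list medians include them. In 2 let-7 members looked at by eye, the last 3 columns against the first 3 gave differences like the fold changes. If the columns follow the order in which the samples are listed, JJ012 first, every sign given here would turn. The columns' order is not stated, so this is left open. The design fixed before the data were examined was a limma comparison of 3 against 3 samples with lists tested by camera, detection calls and replicate alternatives. None of these could be fitted to fold changes without samples, so no p-value, standard error or count of significant miRNAs is given.

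Each signed fold was converted to log2 (JJ012 over C28) with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and figures were drawn with matplotlib 3.10.9. miRNAs were counted as higher or lower, and as at least 2-fold away. This fold limit was set after the table was opened. Exact (Clopper-Pearson) 95% binomial intervals are given for shares of miRNAs. These intervals treat miRNAs as independent, which they are not, and cover counting error only.

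The 28 lists of miRNA families, genomic clusters, reported targeting and cell types were fixed before the data were examined, from general knowledge. A list member was matched by name, leaving out minor arms (names ending in an asterisk). For the 18 lists with at least 3 members in the table, the list's median log2 fold change was placed among 10000 random lists of the same size. Random lists were drawn from the 254 assays that are neither minor arms nor in-house miRPlus assays. They could not be matched on expression level, which the fold table does not hold. The percentile describes these fold changes and is not a test between the lines. Random lists treat miRNAs as independent, so percentiles of lists made of neighbouring genes or of arms of one hairpin overstate how far these stand apart. In simulations on lists of 8, 4.54% of 5000 unshifted lists fell outside the central 95% of random lists. A share of about this size follows by construction, so it checks the calculation only and not the lists of neighbouring genes.

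The rule for named miRNAs, fixed before the data were examined, took the 10 highest and 10 lowest, up to 4 members of each list with the largest change, every let-7 member, and miR-140, miR-143, miR-145, miR-34a, miR-21 and miR-210. Its conditions on significance and on replicates that do not overlap could not be applied. The 10th place among the higher miRNAs was tied, and both are named.

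Genes were matched to miRNAs by symbol or synonym in a table of RefSeq genes on GRCh38.p14, and 308 of 325 miRNAs matched. Since the fold table names no genome build, that table was used only for names and for grouping neighbouring genes, and no coordinates are given. A gene joined a group when its start lay within 10000 bp of the start of the preceding gene used here. Members of 1 group can thus lie further apart. The 274 miRNAs with 1 gene gave 218 hairpin genes, whose arms were averaged. Alternatives were other zero points of the scale, other fold limits, and sets of assays left out or added.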

Results

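miRNA profiles of the JJ012 chondrosarcoma line and the C28 control chondrocyte line were compared by real-time PCR, with 3 samples of each line. Chondrosarcoma is a malignant tumour that forms cartilage matrix, and miRNAs are short RNAs that repress the messenger RNAs they pair with. The series title names loss of miRNA control over the NOTCH and insulin-like growth factor receptor (IGFR) pathways as its subject. The values are fold changes as the authors calculated them, read as JJ012 over C28 because the labels call the JJ012 samples test and the C28 samples control. They carry no replicate error, so whether any difference exceeds the spread between samples could not be tested, and the depth and detection behind each value are unknown. For many of these miRNAs a second table of per-sample values, otherwise unused, showed no reading, so the origin of their fold changes is open.

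JJ012 cells had lower levels than C28 cells of 187 of the 325 miRNAs in the authors' deposited table and higher levels of 138. Among the miRNAs at least 2-fold away, 114 were lower and 48 higher, which is 70.4% lower (exact 95% binomial interval 62.7 to 77.3%) in the authors' deposited table. The direction rests on the labels alone, and were it turned, 114 would be higher and 48 lower in the authors' deposited table, and every other sign here would turn too. At 10-fold or more, the authors' deposited table held 16 lower and 7 higher miRNAs. The median log2 fold change of the authors' deposited table was -0.29. Setting that median to 0 left 56.9% of the miRNAs at least 2-fold away on the lower side, and setting the mean to 0 left 50.3%. With the mean of miR-103, miR-423-5p and miR-191, often used as reference miRNAs, set to 0 the lower side held 76.9%. These references did not move together in the authors' deposited table. There miR-103 was 2.01-fold lower, while miR-423-5p was 1.79-fold and miR-191 1.65-fold higher. Their mean is thus an uncertain zero point, and shares with each of them alone set to 0 were not computed. With miR-103 alone at 0, all 138 higher miRNAs would be at least 2-fold higher. At most the 45 miRNAs at least 4-fold lower as deposited could then remain at least 2-fold lower. The excess would thus turn to the higher side on that zero point.

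**Figure D1:**
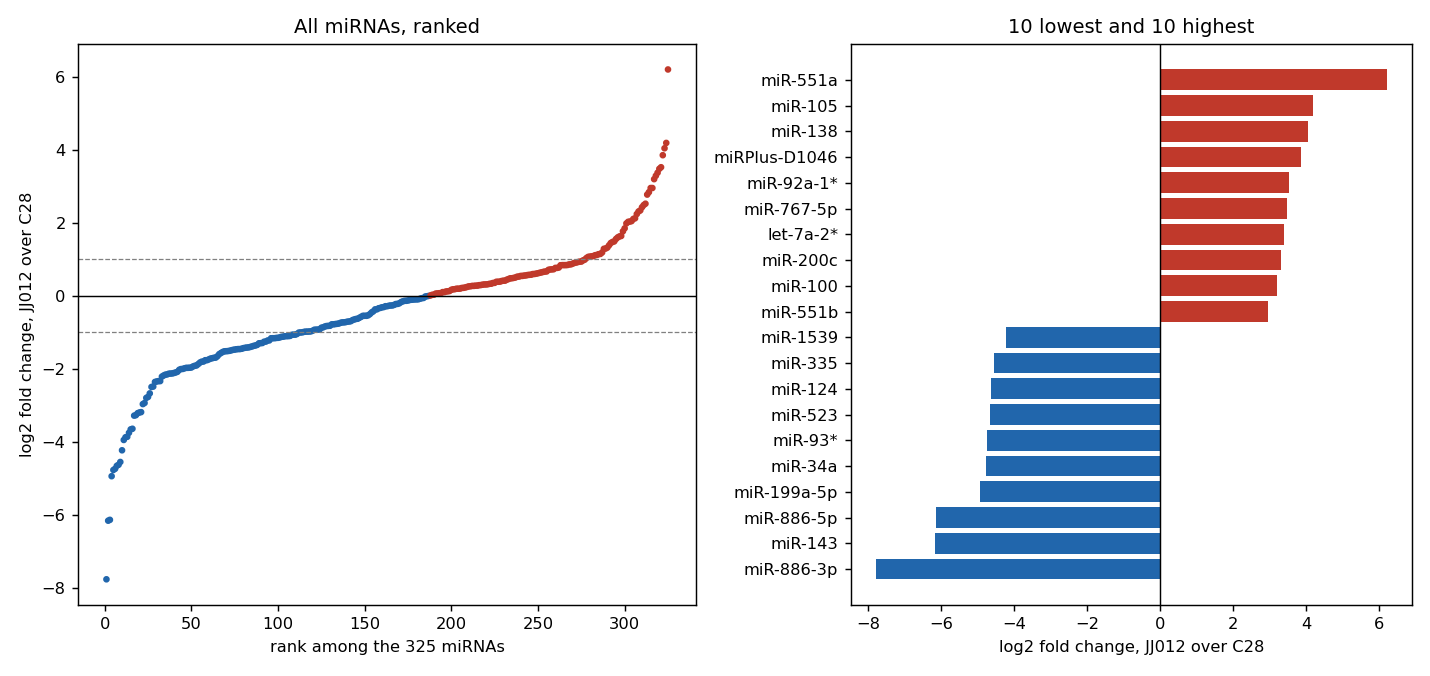
Left, log2 fold change (JJ012 over C28) of the 325 miRNAs ordered by rank, with dashed lines at 2-fold; right, bars for the 10 lowest and 10 highest, red higher and blue lower in JJ012, with no error bars because the table has no replicates. The values run from -7.77 for miR-886-3p to 6.20 for miR-551a.

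Both products named miR-886 were among the 3 lowest values relative to C28. The authors' deposited table gave miR-886-3p as 219-fold lower and miR-886-5p as 70.7-fold lower. RefSeq now lists this gene under a vault RNA name, VTRNA2-1, and not as a miRNA gene name. miR-143, which shares a precursor transcript with miR-145, was 71.8-fold lower in the authors' deposited table. Next in the authors' deposited table were miR-199a-5p at 30.8-fold lower and miR-34a, a p53-induced miRNA, at 27.4-fold lower. The authors' deposited table also listed miR-93* at 26.8-fold, miR-523 at 25.3-fold, the neural miR-124 at 24.8-fold, miR-335 at 23.5-fold and miR-1539 at 18.9-fold lower.

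At the other end, miR-551a was 73.7-fold higher in JJ012 in the authors' deposited table. miR-105 was 18.3-fold and miR-767-5p 11.2-fold higher in the authors' deposited table. Their genes lie close together on the X chromosome. miR-138 was 16.5-fold and miRPlus-D1046, an assay of the manufacturer's own, 14.5-fold higher in the authors' deposited table. The authors' deposited table further held miR-92a-1* at 11.5-fold, let-7a-2* at 10.4-fold, miR-200c at 9.78-fold and miR-100 at 9.17-fold higher. miR-296-3p and miR-551b shared a value of 7.75-fold higher in the authors' deposited table.

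The let-7 family, which represses growth-promoting genes including RAS and the IGF1 receptor gene IGF1R, was divided. The authors' deposited table held 8 members, with 4 higher and 4 lower. let-7a was 4.36-fold, let-7c 2.44-fold, let-7b 2.17-fold and let-7d 1.28-fold higher in the authors' deposited table. In contrast, let-7i was 2.87-fold, let-7g 2.10-fold, let-7e 1.67-fold and let-7f 1.45-fold lower in the authors' deposited table. The family's median log2 fold change of -0.09 stood at percentile 70.7 of random lists. These members differ by few bases, and the assays' ability to separate them was not tested.

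miRNAs reported to target NOTCH receptors, their ligands or the NOTCH-responsive gene HES1 were lower in 8 of 10 cases in the authors' deposited table. miR-199a-5p, miR-34a and miR-124 gave the 3 lowest values, at 30.8-, 27.4- and 24.8-fold lower in the authors' deposited table. Both exceptions in the authors' deposited table were more than 7-fold higher, miR-200c at 9.78-fold and miR-139-5p at 7.16-fold. The list median of -0.77 stood at percentile 33.1 of random lists, within the central 95% of these.

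Leaving out let-7, of the 18 miRNAs reported to target IGF1R, its ligands or its adaptor IRS1, 10 were lower and 8 higher in the authors' deposited table. miR-143 at 71.8-fold, miR-335 at 23.5-fold and miR-148a at 9.19-fold were lower, and miR-100 at 9.17-fold was higher, in the authors' deposited table. miR-145 was 9.13-fold lower in the authors' deposited table. The list median of -0.99 stood at percentile 14.3 of random lists.

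Cartilage-associated miRNAs were mostly lower in JJ012, with 9 of 12 lower and 8 of these at least 2-fold in the authors' deposited table. miR-140, the miRNA most closely tied to chondrocytes, was 5.06-fold lower for its 5p arm and 2.68-fold lower for its 3p arm in the authors' deposited table. miR-146a, induced by inflammatory signals, was 12.5-fold lower and miR-199a-3p 14.6-fold lower in the authors' deposited table. miR-222 at 4.13-fold higher went the other way in the authors' deposited table. The list median of -1.88 stood at percentile 0.32 of random lists. It shares miR-199a-5p and miR-199a-3p with the list of the miR-199a and miR-214 cluster.

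2 other lists of the 18 placed also lay below the central 95% of random lists. Their members come from neighbouring genes or the same hairpin, and the cartilage list holds both arms of miR-140 and of miR-199a. Members of these 3 lists are thus not independent, and the percentiles overstate how far the lists stand apart. Independent lists would put 0.9 of the 18 outside by chance, but the cartilage and miR-199a lists share members and do not count separately. All 3 members of the miR-199a and miR-214 list, which leaves out minor arms, were lower, with miR-214 at 7.67-fold in the authors' deposited table, and their median of -3.87 stood at percentile 0.60. The 14q32 list, named for the imprinted DLK1-DIO3 region, had 17 of 20 members lower in the authors' deposited table and a median of -1.49 at percentile 0.515. It counts miR-345, 3.28-fold lower in the authors' deposited table, whose place within that region was not checked, and leaves out miR-300. The list's lowest members in the authors' deposited table were miR-127-3p at 15.5-fold, miR-134 at 7.83-fold, miR-495 at 5.15-fold and miR-376a at 5.06-fold lower. The 3 higher members, miR-412, miR-485-3p and miR-665, named after their values were seen, were within 2-fold in the authors' deposited table.

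**Figure D2:**
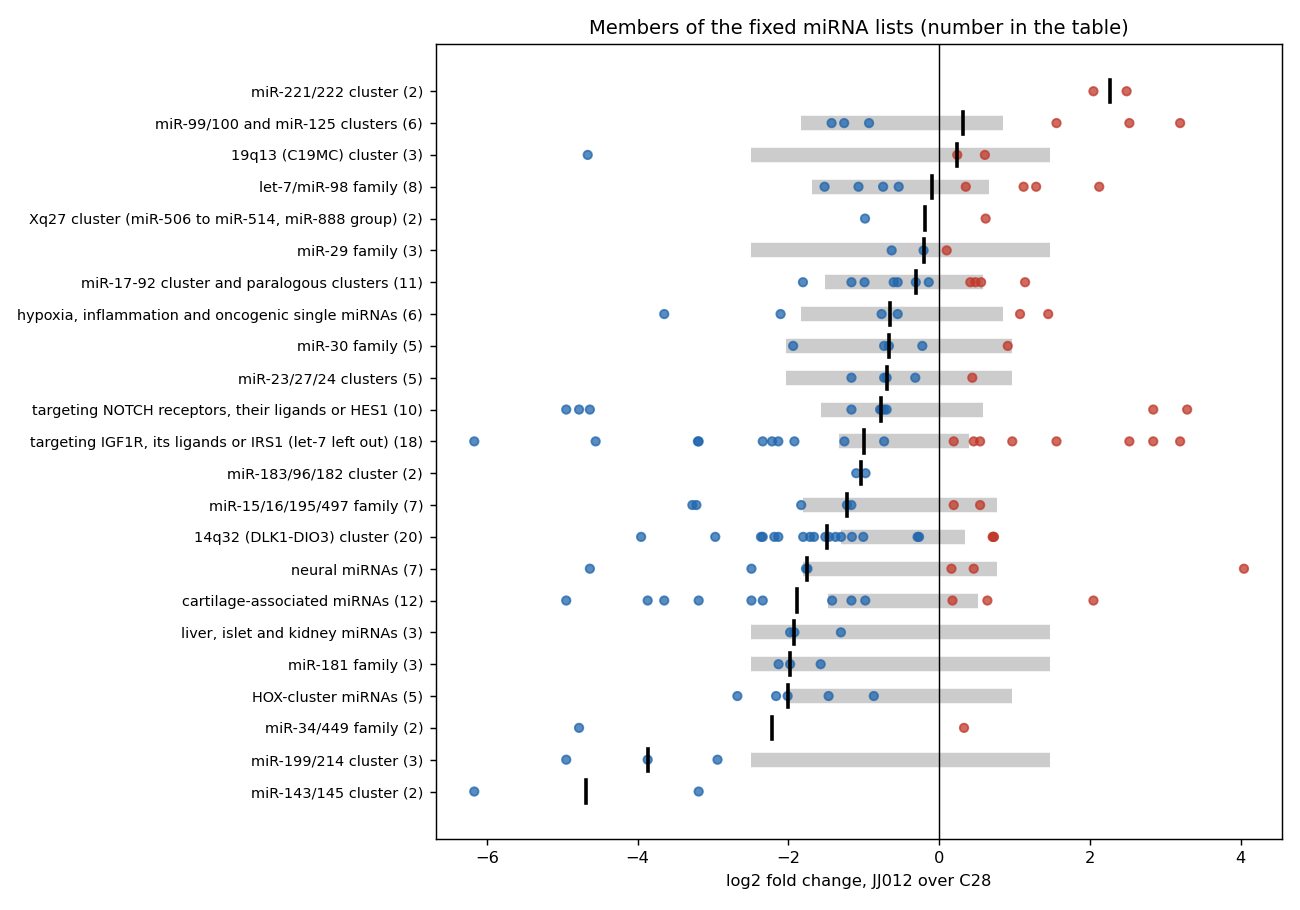
Log2 fold change (JJ012 over C28) of each member of the lists with at least 2 members in the table, red higher and blue lower in JJ012; the black bar is the list median and the grey band the central 95% of 10000 random lists of that size, drawn for lists of 3 or more. The medians of the cartilage-associated, miR-199a with miR-214, and 14q32 lists lie below their bands.

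Several smaller clusters and families lay wholly on one side. All 5 HOX-cluster miRNAs were lower in the authors' deposited table, among them miR-10a at 6.39-fold and miR-615-3p at 4.48-fold, with a median of -2.01 at percentile 2.72. The 3 miR-181 members were lower, miR-181a by the most at 4.38-fold in the authors' deposited table, with a median of -1.98 at percentile 6.88. Both miR-221 at 5.61-fold and miR-222 at 4.13-fold were higher in the authors' deposited table. Both miR-182 at 2.14-fold and miR-96 at 1.97-fold were lower in the authors' deposited table.

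The growth-suppressing miR-15 and miR-16 family, with miR-195 and miR-497, had 5 of 7 members lower in the authors' deposited table, led by miR-503 at 9.67-fold and miR-15a at 9.32-fold, with a median of -1.22 at percentile 15.97. The growth-promoting miR-17-92 cluster and its paralogs, leaving out minor arms, had 8 of 11 members within 2-fold in the authors' deposited table. The share for all miRNAs, minor arms included, was 163 of 325. The list median was -0.31 at percentile 58.8. Within the list miR-93 at 3.50-fold and miR-19a at 2.24-fold were lower and miR-92a was 2.20-fold higher in the authors' deposited table. Of the minor arms left out, miR-93* was 26.8-fold lower, and miR-92a-1* at 11.5-fold and miR-18a* at 2.13-fold were higher. The minor arms miR-17*, miR-20a*, miR-19b-1*, miR-25* and miR-106b* were within 2-fold in the authors' deposited table. The miR-99/100 and miR-125 list was split in the authors' deposited table, with 3 members higher and 3 lower, and its median of 0.31 stood at percentile 85.4. miR-100 at 9.17-fold, miR-125b at 5.75-fold and miR-99a at 2.94-fold were higher in the authors' deposited table. miR-125a-5p at 2.69-fold, miR-125a-3p at 2.39-fold and miR-99b at 1.91-fold were lower in the authors' deposited table.

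The medians of 3 further families lay within the central 95% of random lists. The miR-30 family median of -0.67 stood at percentile 45.4, that of the miR-23/27/24 clusters, -0.70, at percentile 44.6, and that of the miR-29 family, -0.21, at percentile 59.2. Leaving out minor arms, the authors' deposited table held 2 members of the miR-34 and miR-449 family, too few to place among random lists. These were miR-34a at 27.4-fold lower and miR-34c-3p at 1.26-fold higher in the authors' deposited table. Of the minor arms, miR-34a* was 3.97-fold lower and miR-449b* 1.91-fold higher in the authors' deposited table. Among single miRNAs linked to hypoxia, inflammation or tumours, the list median was -0.66 at percentile 40.5. In the authors' deposited table miR-21 was 1.70-fold and the hypoxia-induced miR-210 1.46-fold lower, miR-146b-5p was 4.30-fold lower, and miR-31 at 2.73-fold and miR-155 at 2.10-fold were higher.

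Of lists typical of other cell types, which leave out minor arms, the authors' deposited table held 1 of 8 epithelial names, miR-200c, at 9.78-fold higher. The minor arm miR-141*, from the gene next to that of miR-200c, was 1.13-fold higher. Of muscle names 1 of 7 was held, miR-499-3p, at 2.16-fold higher in the authors' deposited table. Of blood cell names 1 of 7 was held, miR-486-3p, at 1.46-fold higher in the authors' deposited table. The endothelial miR-126 was 3.40-fold lower in the authors' deposited table. Among the 7 neural members, 4 were lower in the authors' deposited table, including miR-124 at 24.8-fold and miR-9 at 5.62-fold, while miR-138 was 16.5-fold higher, and the median of -1.75 stood at percentile 3.49. All 3 liver, islet and kidney members, miR-192, miR-194 and miR-215, were lower in the authors' deposited table, with a median of -1.92 at percentile 8.13. The placental 19q13 (C19MC) cluster had 3 members in the authors' deposited table, of which miR-523 was 25.3-fold lower, and a median of 0.24 at percentile 72.5, opposite in sign to its mean of -1.27. The Xq27 list had 2 members in the authors' deposited table, miR-509-3p at 1.98-fold lower and miR-891b at 1.53-fold higher, and the pluripotency list had none.

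Neighbouring miRNA genes, which can be transcribed together, were set side by side in 26 groups that held 79 of the 218 hairpin genes. MIR143 and MIR145 gave the lowest group median, -3.50, and MIRLET7A2 and MIR100 the highest, 3.29, from the authors' deposited table.

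**Figure D3:**
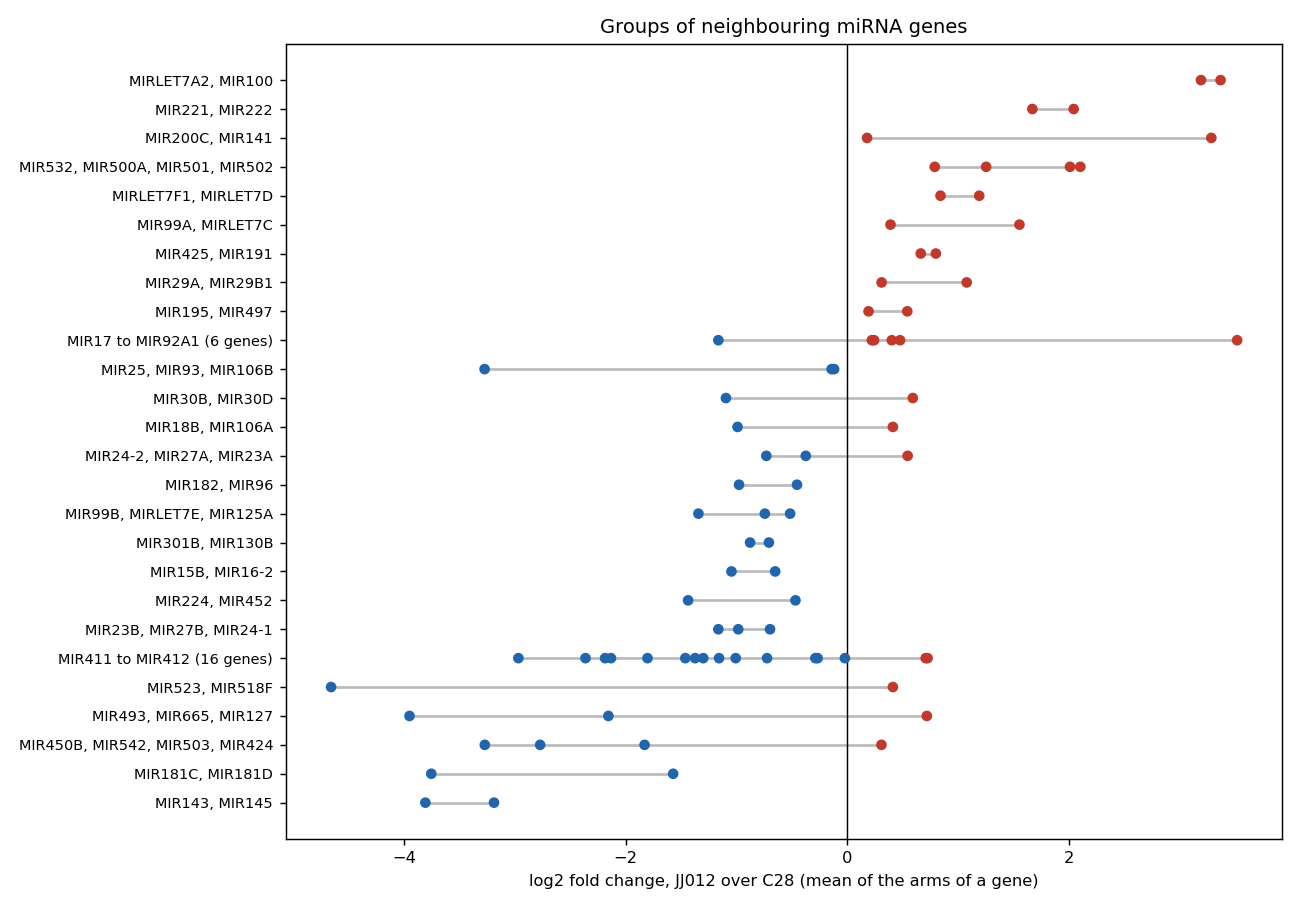
Log2 fold change (JJ012 over C28, mean of the listed arms) of each miRNA gene in the 26 groups of neighbouring genes, ordered by group median. Within a group, each gene's start lies within 10000 bp of the preceding gene's start. Red points are higher and blue lower in JJ012, and grey lines span a group. The group of MIR143 and MIR145 lies lowest and that of MIRLET7A2 and MIR100 highest.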

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

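All alternatives were chosen after seeing the data except the zero point set on miR-103, miR-423-5p and miR-191. Assuming 1 reference for every assay, the zero points moved every log2 fold change by 0.29 (table median set to 0), 0.43 (table mean set to 0) or -0.18 (those 3 miRNAs set to 0). The 48 miRNAs at least 2-fold higher became 80 with the mean set to 0, 79 at a fold limit of 1.5 and 24 at a limit of 4, and the 114 lower became 45 at a limit of 4. The other 10 counts stayed within 1.5 times. With the 3 miRNAs set to 0, 100% of the miR-29 list was lower, and the other 68 list shares stayed within their exact 95% binomial intervals, which are wide. Of 91 miRNAs under the naming rule, 2 changed sign: miR-29a became -0.084 with the 3 miRNAs set to 0, and miR-29c became 0.08 with the median and 0.22 with the mean set to 0. The rule mostly takes large changes and the zero points moved values by 0.43 at most, so few could change sign. Sign changes among the other miRNAs were not counted. No paired analysis was possible because the fold changes carry no samples. For the same reason leave-one-out, the cycle limits, undetected-well rules, quantile, panel and small nuclear RNA normalizations, limma settings, camera and fry were not run, and no agreement with the authors' table was computed. Stability against replicate error is therefore unknown.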

Other observations

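The tests of neighbouring genes were chosen after values of several clusters had been seen; those of arms, grid and zero point were written before their results were seen. The miRNAs named here that the report does not name were chosen after their values were seen. The only biological explanation tested was a shared precursor for the arms of a hairpin.

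Several groups of neighbouring miRNA genes lay wholly or mostly on one side in the authors' deposited table. let-7a-2* at 10.4-fold and miR-100 at 9.17-fold, from neighbouring genes, were both higher in the authors' deposited table. The 4 neighbouring genes MIR532, MIR500A, MIR501 and MIR502 were all higher, with miR-532-3p at 5.38-fold and miR-500 at 4.31-fold in the authors' deposited table. Of MIR450B, MIR542, MIR503 and MIR424, 3 were lower, with miR-503 at 9.67-fold in the authors' deposited table.

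Of 53 pairs of adjacent neighbours, 41 had the same direction, where shuffling the values over genes gave 51.7%. Their median absolute log2 difference was 0.99 against 1.03 to 1.97 in the central 95% of shuffles. The largest group alone does not account for this, since the difference was 0.69 over 38 pairs without the 16-gene group of 14q32 (shuffles 0.98 to 2.05). The group of MIR493, MIR665 and MIR127, also on the 14q32 list, stayed in. Cross-reaction between assays of one sequence family cannot be told apart from joint transcription: over the 25 pairs of different families the difference was 0.97, within the shuffled 0.86 to 2.24, and 18 pairs had the same direction, at the upper end of the shuffled 8 to 18. A looser split by miRNA number, tried first, left 49 pairs at 0.99 against a lower bound of 1.01, so this answer depends on how families are drawn.

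The 2 arms of a hairpin also went together in 41 of 56 pairs, where shuffling gave 50.03%. Their median absolute difference was 0.77 against 0.985 to 1.67 in the central 95% of shuffles, which is consistent with control of the shared precursor. Exceptions in size were miR-143, 71.8-fold lower against 2.74-fold for miR-143*, and miR-93, 3.50-fold lower against 26.8-fold for miR-93*, in the authors' deposited table. Another was miR-34a, 27.4-fold lower against 3.97-fold for miR-34a* in the authors' deposited table. The remaining 15 pairs went in opposite directions. Among them, miR-30e was 3.83-fold lower and miR-30e* 1.02-fold higher in the authors' deposited table. Likewise, let-7c was 2.44-fold higher and let-7c* 1.42-fold lower in the authors' deposited table. Not among the 56 pairs was miR-105, 18.3-fold higher although miR-105* was 2.18-fold lower in the authors' deposited table. The 56 pairs do include the products named miR-886, whose gene RefSeq lists as VTRNA2-1. Minor arms were lower in 44.8% of 67 cases (exact 95% interval 32.6 to 57.4%) and other assays in 60.6% of 254 (54.3 to 66.7%).

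More miRNAs were at least 2-fold lower than higher on the deposited scale. Counting each group of neighbouring genes and each lone gene once, 58 of 79 loci at least 2-fold away were lower, 73.4% (exact 95% interval 62.3 to 82.7%). Genes with no neighbour among the 218 placed gave 52 of 68 lower and the groups themselves 6 of 11. This argues against a few of the groups, as drawn, supplying the excess. Genes of miRNAs matched to several genes were left out. Some of these lone genes, MIR214 and MIR767 among them, thus have neighbours that were not counted, and clusters broken up in this way were not tested. The 14q32 list was also split, with MIR127, MIR370 and MIR134 in separate loci that each counted once. The zero point of the scale cannot be told apart from a difference between the lines. The share was 56.9% (48.8 to 64.7%) with the table median set to 0, where centring itself pulls the split towards even. It was 76.9% (69.8 to 83.0%) with the mean of miR-103, miR-423-5p and miR-191 set to 0. Those references lay apart, with log2 fold changes of -1.01 for miR-103, 0.84 for miR-423-5p and 0.72 for miR-191. The share on that zero point therefore depends on which references are averaged. With miR-103 alone set to 0, the excess would lie on the higher side.

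All 325 log2 fold changes lay on one grid of 600 steps per log2 unit, within 0.01 of a step, and 296 of them on every second step. Differences between means of 3 readings given to 0.01 cycle, less 1 common constant, would produce such a grid, and a mean of 2 readings would produce the intermediate step seen in 29 values. In simulated random values 1.75% lay on the grid. This is consistent with 1 reference for every assay, although references a whole number of steps apart would look alike, and with 2 readings in 1 line for at least some miRNAs, among them miR-523. Their median absolute log2 fold change was 0.94, against 0.65 to 1.47 in random sets of 29, which does not bear on whether they are more variable, since the size of a fold change also holds the difference between the lines.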
